A study of Homo sapiens with 8 samples.

How the data were processed

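Gene expression was measured with 8 Affymetrix Human Gene 1.0 ST arrays, a whole-transcript array with several short probes per gene summarised into probe sets. Each array carried RNA of 1 sorted population of 1 human tumour cell line, so that 4 arrays were labelled ABCB5-positive and 4 ABCB5-negative. Per the labels' protocols, the cells grew in RPMI medium with serum and antibiotics, were sorted by fluorescence with an antibody against the transporter ABCB5, and gave total RNA through a Qiagen column kit, which was amplified with the Ambion WT kit and labelled with biotin. The sample labels name the lines COLO741, SW620, HT29 and HCT116, all described as colon carcinoma, while the series design text names SW480 where the sample labels name SW620. The sample labels were followed, and which name is right was not settled.

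The values the authors deposited are log2 expression values, 1 per probe set and array, for 33297 probe sets with 0 missing values. The log2 scale was read from their range of 2.99 to 15.24, since the labels do not state it. Per the submitters' processing notes they were made with Affymetrix Expression Console. Its version, the summarisation algorithm, the background correction and the normalization are not given in the sources used here. The array medians lay between 8.03 and 8.10, so the arrays were on nearly 1 scale as deposited, and no further normalization was applied for the values reported. The number of arrays limits the precision, and no depth applies to this kind of data.

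Probe sets were named through the platform annotation, which can be old, with symbols brought up to date through gene identifiers of the assembly GRCh38.p14, used for names and for the order of neighbouring genes and for no coordinate. Of the probe sets, 19460 named 1 gene, 1754 named several and were not used for a gene, and 12083 were not listed and stayed unnamed. A gene identifier matched for 19429 of those naming 1 gene and not for 31, which kept the annotation's symbol. The named probe sets covered 18417 genes, and for the 769 genes with more than 1 probe set the probe set with the highest mean over the 8 arrays was taken. Dimness was judged against 360 probe sets of olfactory receptor genes, a family used in the nose, whose means had a median of 5.73. Genes with a mean below that median were left out, 1507 in all, and 16910 genes were tested.

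The populations were compared with limma 3.58.1 in R 4.3.3, by a linear model per gene with the cell line as a fixed block, moderated variances, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The block rests on the labels, which give both populations of a replicate number the same cell line. As a check of the pairing, the deviations of the 2 arrays of a line from their group means correlated at 0.932 to 0.963 across genes. The model left 3 residual degrees of freedom, to which the moderation added 3.44. For ABCB5 an exact sign-flip permutation test over the 4 lines was added. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists, with an estimated correlation and the rotation test fry as alternatives. Each list's median in a single line was set against 10000 random lists of the same size, drawn from 20 bins of mean level. The random lists draw genes independently, so a list whose genes vary together can reach an extreme percentile. Differences between cell lines were tested in the same kind of model with the sorted population as covariate. Single lines have 1 array per population and were described without a test.

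The lists were ABC transporters of drugs and lipids, intestinal stem cell markers, Wnt targets, anti-apoptotic genes, pro-apoptotic genes, p53 targets, G2/M and mitosis genes, DNA replication and S phase genes, epithelial genes, mesenchymal and invasion genes, enterocyte and goblet cell genes, melanocyte genes, leukocyte genes, fibroblast and endothelial genes, immediate early genes, heat shock genes, unfolded protein and integrated stress response genes, hypoxia and glycolysis genes, cholesterol synthesis genes, interferon-stimulated genes, NF-kB targets, glutathione and NRF2 targets, fluoropyrimidine metabolism and DNA repair genes, cytosolic ribosomal protein genes, respiratory chain genes, receptor tyrosine kinases and ligands, small nucleolar RNA genes, replication-dependent histone genes and olfactory receptor genes. Another 3 lists, of macrophage and monocyte transcripts, of T, B and NK cell transcripts and of small nuclear and other small RNA genes, were added after the data had been seen.

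The genes named are ABCB5 and every list member past the threshold, up to 12 genes per direction past the threshold with 1 sign in all 4 lines, with open places filled by the smallest unadjusted p among genes of 1 sign, the 2 members of smallest unadjusted p of each list, the 8 largest differences per direction between COLO741 and the other lines, and the 3 largest per direction in each line. Small nucleolar RNAs, names starting with LOC and members of clustered families are marked as such. Other genes named were chosen after their values were seen, as is said there. The groups, tests, 29 lists, naming rule and alternatives were fixed before the data were examined, except where a later choice is stated.

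The alternatives were no block, the line as a random block, no filter and a filter at the 95th percentile of the olfactory receptor probe sets, quantile normalization, median centring, variances with an intensity trend, robust variances, ordinary least squares, the mean of a gene's probe sets, every probe set, other thresholds, and leaving out each line in turn. A setting without COLO741 and SW620 together was added after the data had been seen. For the order of genes along chromosomes, differences of neighbouring genes were correlated by rank and set against 1000 shuffles of the gene order, and standard errors of medians came from 2000 bootstrap draws. The methods were tested on simulated data for the comparison of populations, with 16910 genes, independent of each other unlike real ones, 50 changed genes per fold size and 20 simulations. Of genes changed 1.5-fold 68.0% were recovered, of those changed 2-fold 95.1%, 4-fold 99.4% and 8-fold 99.7%, with 9.75 false calls per simulation. Each simulated change was equal in all lines, and each gene had 1 noise level for all lines. In the data the SD of the differences across genes was 0.32 in COLO741 and 0.15 in HCT116. These shares therefore do not carry over to changes that differ between lines. A list shifted by 0.3, a larger shift than the median of any list called below, was found in 20 of 20 simulations. Data without a change gave 0.1 genes and 0.05 lists per simulation.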

Results

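Transcripts of sorted tumour cells were profiled to compare cells with and without ABCB5, an ATP-binding cassette transporter that the series title ties to resistance against apoptosis. The lines were COLO741, SW620, HT29 and HCT116, established human lines that the labels describe as colon carcinoma. Each line gave 1 array labelled ABCB5-positive and 1 labelled ABCB5-negative, so that each group held 4 arrays. Both arrays of a line resembled each other closely, with correlations across all probe sets of 0.993 to 0.996, against 0.931 to 0.965 between the ABCB5-negative arrays of different lines. Nothing in the labels says that the arrays come from separate cultures beyond being separate lines, so the p-values of single genes measure the spread between these pairs, part of which may be technical. The p-values of gene lists at the preset correlation instead treat the genes of a list as nearly independent.

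ABCB5 itself, measured by probe set 8131682, was bright in COLO741 and dim in the other 3 lines. In COLO741 its log2 level was 9.42 in the array labelled ABCB5-negative and 8.14 in the array labelled ABCB5-positive, 2.42-fold lower and opposite to the labels. In SW620, HT29 and HCT116 the ABCB5 level lay between 5.24 and 5.69 on all 6 arrays, below the median of 5.73 of the olfactory receptor probe sets. The differences of ABCB5, array labelled positive minus array labelled negative, were -1.28 in COLO741, 0.10 in SW620, -0.12 in HT29 and 0.29 in HCT116. Since 3 of these come from values at background, only COLO741 measures a difference of the ABCB5 transcript, and the mean over the lines, -0.25 ± 0.70 (SD, n = 4), does not test it. By an exact two-sided sign-flip permutation test that mean had p = 0.75, where 0.125 is the smallest p that 4 lines allow. The adjusted p of ABCB5 from limma was 0.906. Without COLO741 the mean was 0.09 ± 0.20 (SD, n = 3), all of it at background. The sort was on the protein, which the arrays do not measure, and each direction drawn from COLO741 below rests on labels that its ABCB5 transcript opposes.

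**Figure D1:**
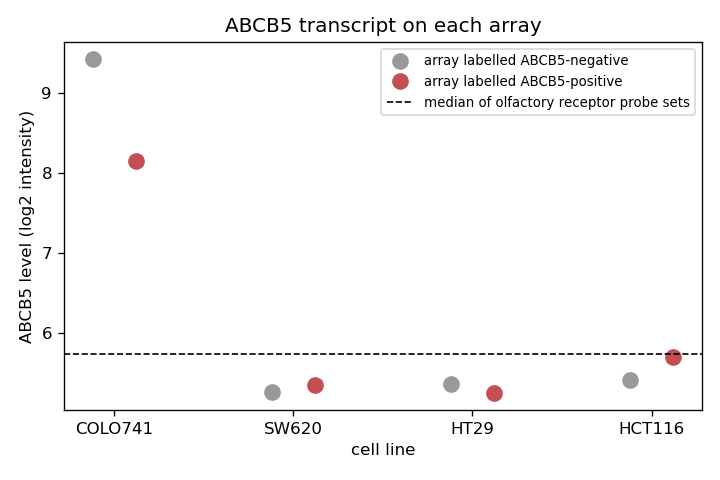
Log2 level of the ABCB5 transcript (vertical axis) in each cell line (horizontal axis), 1 point per array, grey for arrays labelled ABCB5-negative and red for arrays labelled ABCB5-positive, with the olfactory receptor median of 5.73 as a dashed line. The COLO741 arrays sit at 9.42 (negative) and 8.14 (positive), and the other 6 arrays lie below the dashed line.

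The comparison of the populations over all lines asked which genes go with the ABCB5 label, and with limma 0 of 16910 genes passed, while 744 had an unadjusted p under 0.05. The steadiest higher values, none past the threshold, included TM4SF18, a membrane protein of the tetraspan family, at 0.56 ± 0.08 (log2, SD, n = 4), and TGM2, a transglutaminase that crosslinks proteins, at 1.12 ± 0.61 or 2.17-fold. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, measured 0.47 ± 0.13 higher and HJURP, the chaperone of the centromeric histone, 0.41 ± 0.18 higher. ITGB6, an integrin subunit of epithelia, measured 0.39 ± 0.13, and the galactosyltransferase gene B3GALT5 0.33 ± 0.10. Among genes known to respond to interferon, XAF1 measured 0.36 ± 0.11 and PSMB8, a subunit of the immunoproteasome, 0.30 ± 0.09. The other places went to IFITM10 at 0.32 ± 0.05, NCOR1P1, a pseudogene, at 0.35 ± 0.12, and CYP4A22 at 0.35 ± 0.13 and ZNF570 at 0.39 ± 0.15, both of clustered gene families.

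On the lower side RAB39A, a small GTPase of vesicle traffic, measured -0.60 ± 0.16 (log2, SD, n = 4), and the antisense transcript LIMD1-AS1 -0.55 ± 0.11. SYT17, a synaptotagmin, measured -0.40 ± 0.16, PRTG, a receptor of the immunoglobulin family, -0.38 ± 0.07 and the receptor gene GPR151 -0.31 ± 0.09. PYCARD, the adaptor that links inflammasome sensors to caspase-1, measured -0.27 ± 0.06. PAGE1, of a clustered family, measured -0.35 ± 0.14, and ANKRD20A11P, a pseudogene, -0.32 ± 0.13. The small nucleolar RNAs SNORD59A, SNORA29, SNORD12C and SNORD81 measured -0.39 ± 0.16, -0.37 ± 0.15, -0.31 ± 0.11 and -0.26 ± 0.05. All 24 of these genes had 1 sign in all 4 lines because the naming rule asked for it, and each had a limma adjusted p of 0.898. Of the 24, 13 had both arrays of at least 1 line under the 95th percentile of the olfactory receptor probe sets, so that background enters their means and no fold is given for them. These were TM4SF18, ITGB6, XAF1, ZNF570, NCOR1P1, CYP4A22, PSMB8, LIMD1-AS1, RAB39A, PRTG, SNORA29, GPR151 and PAGE1.

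With limma, 0 genes passed an adjusted p of 0.05 or 0.1, and the lowest adjusted p was 0.898. The genes with unadjusted p under 0.05 numbered 744, of which 443 were higher and 301 lower, against 845.5 by chance alone. The count past the adjusted threshold was also 0 without the cell line in the model, with the line as a random block and by ordinary least squares, where 27, 775 and 704 genes had such an unadjusted p. An unadjusted p under 0.01 with at least a 1.5-fold difference picked 5 genes, TGM2, RAB39A, IFI44 and, named after their values were seen, the chloride channel gene ANO1 (0.70 ± 0.52) and TRIM29 (0.68 ± 0.52). The number of genes with unadjusted p under 0.01 and at least 1.5-fold was 8 without SW620 and 23 without HCT116. The median standard error of a difference was 0.08 on the log2 scale.

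Shifts of whole gene groups asked whether known programs go with the label, and 5 of the 29 lists passed at the preset correlation. With an estimated correlation 0 lists passed, at a lowest adjusted p of 0.548, and by fry 0. The G2/M and mitosis genes rose, with 28 of 30 higher and a median of 0.18. CDK1, the kinase that drives entry into mitosis, measured 0.49 ± 0.28 (SD, n = 4), UBE2C 0.47 ± 0.13, TOP2A, the topoisomerase of dividing cells, 0.30 ± 0.19 and AURKB, a mitotic kinase, 0.27 ± 0.11 (the last 2 named after their values were seen). The adjusted p from limma's camera was 1.00e-14 at the preset correlation and 0.580 with an estimated correlation. Over all genes tested 0 of the 30 genes passed, 11 had an unadjusted p under 0.05, and 1, UBE2C, passed adjusted over the list alone.

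The replication-dependent histone genes rose as well, with 53 of 63 higher and a median of 0.13. H2BC10 measured 0.42 ± 0.28 (SD, n = 4) and H4C4 0.32 ± 0.17, both of a clustered family of near-identical copies that probe sets may not separate. The adjusted p was 1.02e-12 at the preset correlation and 0.548 with an estimated correlation, and 0 genes passed over all genes or adjusted over the list alone, with 17 at an unadjusted p under 0.05. Small nucleolar RNA genes, which guide the modification of ribosomal RNA and lie mostly within introns of host genes, fell, with 126 of 145 lower, 41 of them in all 4 lines, and a median of -0.14. Their adjusted p was 2.31e-20 at the preset correlation and 0.548 with an estimated correlation, with 0 genes past over all genes or adjusted over the list alone and 38 at an unadjusted p under 0.05. In the arrays labelled positive, 128 other short RNA genes had a median of -0.04.

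The interferon-stimulated genes rose, with 19 of 23 higher and a median of 0.14. IFI44 measured 0.72 ± 0.42 (SD, n = 4), OAS2, a sensor of double-stranded RNA, 0.35 ± 0.18 and IFI6 0.38 ± 0.22. Their adjusted p was 6.87e-07 at the preset correlation and 0.548 with an estimated correlation. Over all genes 0 of the 23 genes passed, 8 had an unadjusted p under 0.05, and 3, IFI44, IFI6 and OAS2, passed adjusted over the list alone. In SW620, leukocyte genes were higher by a median of 0.36 beside the interferon-stimulated median of 0.17 in that line.

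Mesenchymal and invasion genes rose by a median of 0.10, with 24 of 29 higher. AXL, a receptor tyrosine kinase, measured 0.57 ± 0.57 (SD, n = 4), with 1.12 in COLO741 and 1.01 in HT29 but 0.11 in SW620 and 0.05 in HCT116, and PLAU, the urokinase gene, measured 0.35 ± 0.23. The list's adjusted p was 2.21e-04 at the preset correlation and 0.548 with an estimated correlation, and 0 genes passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. The adjusted p of mesenchymal and invasion genes was 0.239 without the cell line in the model and 0.0630 with the line as a random block, and 0.0564 without COLO741 and SW620, a setting chosen after the data were seen, so that the call was lost in all 3. Over all alternatives it ran from 1.97e-05 to 0.548.

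With an estimated correlation and by fry, where 0 lists passed, 2 lists by either method had an unadjusted p under 0.05. The 5 medians kept 1 sign in all 4 lines and were nearest 0 in HCT116 for every list but the small nucleolar RNA genes, whose medians were -0.28 in COLO741, -0.06 in SW620, -0.08 in HT29 and -0.17 in HCT116. For the G2/M genes they were 0.32 in COLO741, 0.17 in SW620, 0.15 in HT29 and 0.02 in HCT116. The HCT116 medians of the mesenchymal and interferon-stimulated lists were 0.003 and 0.03, only at percentiles 72.1 and 79.3 of random lists. In COLO741, where ABCB5 opposed the label, 4 of the 5 medians lay farthest from 0. With the 2 COLO741 arrays exchanged, 1 list passed at the preset correlation, the DNA replication and S phase genes at an adjusted p of 0.0288 from limma's camera, and 0 of the 5. With COLO741 left out, 6 lists passed, the 5 among them.

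**Figure D2:**
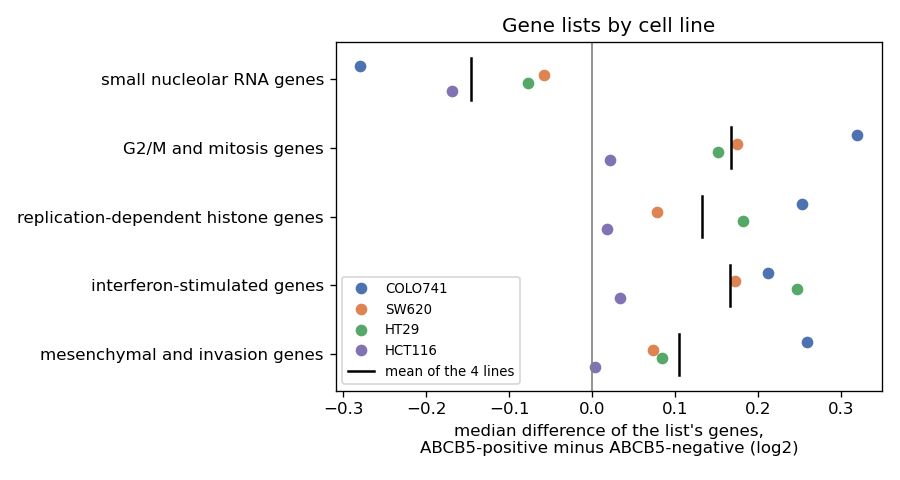
Median difference of each list's genes (log2, array labelled ABCB5-positive minus array labelled ABCB5-negative, horizontal axis) for the 5 lists that passed at the preset correlation, 1 point per cell line and a bar at the mean of the 4 lines. The small nucleolar RNA genes lie below 0 in all 4 lines and the other lists above it, with the G2/M median running from 0.02 in HCT116 to 0.32 in COLO741. The mesenchymal median in HCT116, at 0.003, lies close to 0.

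Neither list of apoptosis genes, the subject of the series title, passed the test. Of 18 anti-apoptotic genes 11 were higher, with a median of 0.02 (adjusted p = 0.879), and of 30 pro-apoptotic genes 16 were higher, with a median of 0.01 (adjusted p = 0.931). FAS, the death receptor, measured 0.34 ± 0.32 (SD, n = 4) and BAK1, a pore-forming protein of mitochondria, -0.20 ± 0.15, while without COLO741 the difference of FAS was 0.19 and the difference of BAK1 was -0.13. The inhibitors API5 and TRAF1 measured -0.11 ± 0.02 and 0.09 ± 0.08. For p53 targets the median was -0.02 and the mean 0.02 (adjusted p = 0.879), with PLK2 at 0.26 ± 0.19 and DDB2 at 0.24 ± 0.18. Unadjusted p was under 0.05 for 0, 5 and 3 genes of these lists. In all 24 lists short of the threshold 0 genes passed, over all genes or adjusted over the list alone, and their p-values are those of limma's camera at the preset correlation.

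Transporter, stem cell and differentiation genes also stayed short of the threshold. ABC transporters of drugs and lipids, which passed over every probe set, had a median of 0.03 (adjusted p = 0.181, and 0.858 with an estimated correlation), with TAP1, a peptide transporter of antigen presentation, at 0.21 ± 0.14 (SD, n = 4) and ABCA3 at 0.22 ± 0.20. Intestinal stem cell markers had a median of 0.02 (adjusted p = 0.990), with the marker LGR5 at -0.15 ± 0.21 and SLC12A2 at -0.13 ± 0.20. Wnt targets had a median of 0.02 and a mean just below 0 with the test pointing down (adjusted p = 0.931), and ETS2 measured -0.18 ± 0.21 and CCND1, cyclin D1, 0.14 ± 0.12. Epithelial genes had a median of 0.02 (adjusted p = 0.931), with LGALS4 at -0.15 ± 0.04 and OVOL1 at -0.17 ± 0.17. Enterocyte and goblet cell genes had a median of 0.01 (adjusted p = 0.931), with DPP4 at -0.27 ± 0.24 and SLC26A3 at 0.14 ± 0.07. Melanocyte genes had a median of -0.07 (adjusted p = 0.674), with MLANA at -0.29 ± 0.33 and MC1R at 0.16 ± 0.07. Leukocyte genes had a median of 0.10 (adjusted p = 0.130), with LAPTM5 at 0.51 ± 0.49 and CD79A at 0.17 ± 0.11, and passed without COLO741, without HT29, with no filter, with the strict filter and over every probe set, though not with an estimated correlation (adjusted p = 0.858). Fibroblast and endothelial genes had a median of 0.00 (adjusted p = 0.601), with ACTA2 at 0.18 ± 0.10 and FAP at 0.16 ± 0.22.

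Among growth, stress and signalling genes, DNA replication and S phase genes had a median of 0.01 (adjusted p = 0.739), with CDC45 at 0.19 ± 0.14 (SD, n = 4) and MCM6 at -0.11 ± 0.10, both of the replicative helicase. Receptor tyrosine kinases and ligands had a median of 0.09 (adjusted p = 0.181), with TGFA at 0.31 ± 0.25 and ERBB4 at -0.19 ± 0.09, and passed without HCT116 and over every probe set, though not with an estimated correlation (adjusted p = 0.858). NF-kB targets had a median of 0.05 (adjusted p = 0.181), with IL1B at 0.79 ± 1.09 and NFKB2 at 0.21 ± 0.16. IL1B rested on COLO741, and without that line the difference of IL1B was 0.26. Immediate early genes had a median of 0.00 with the test pointing down (adjusted p = 0.931), with EGR1 at -0.44 ± 0.29 and FOSB at -0.14 ± 0.13. Heat shock genes had a median of -0.02 (adjusted p = 0.879), with CHORDC1 at -0.16 ± 0.17 and HSPA1L at 0.11 ± 0.12. Unfolded protein and integrated stress response genes had a median of -0.04 and a mean of 0.05 (adjusted p = 0.931), with DDIT4 at 0.50 ± 0.57 and CHAC1 at 0.21 ± 0.16.

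In metabolism, cholesterol synthesis genes had a median of -0.05 (adjusted p = 0.134), with HMGCS1 at -0.21 ± 0.20 (SD, n = 4) and SC5D at -0.19 ± 0.13, and passed without SW620 and without COLO741 and SW620 together, though not with an estimated correlation (adjusted p = 0.858). Hypoxia and glycolysis genes had a median of 0.04 (adjusted p = 0.272), with VEGFA at 0.41 ± 0.49 and HK2, a hexokinase, at -0.24 ± 0.22. Glutathione and NRF2 targets had a median of 0.02 (adjusted p = 0.601), with AKR1C2 at 0.18 ± 0.15 and FTL at -0.24 ± 0.31, and fluoropyrimidine metabolism and DNA repair genes a median of 0.03 (adjusted p = 0.601), with MSH6 at -0.17 ± 0.07 and TK1 at 0.16 ± 0.10. Cytosolic ribosomal protein genes had a median of -0.02 (adjusted p = 0.601), with RPS25 at -0.08 ± 0.07 and RPS7 at -0.09 ± 0.14, and respiratory chain genes a median of -0.01 (adjusted p = 0.767), with CYC1 at 0.20 ± 0.16 and UQCRC1 at 0.12 ± 0.09. Olfactory receptor genes, a clustered family that passed without HCT116, had a median of -0.02 (adjusted p = 0.601, and 0.969 with an estimated correlation), with OR3A3 at -0.28 ± 0.21 and OR1N1 at -0.28 ± 0.24.

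Single lines weighed on many of the means given for genes. Of the 79 genes named by a mean over the lines, 21 had a mean level under the 95th percentile of the olfactory receptor probe sets. Beside 9 of the 24 steadiest genes, these were TRAF1, DPP4, SLC26A3, FAP, HSPA1L, IFI44, OAS2, IL1B, ERBB4, H2BC10, OR3A3 and OR1N1. Of the same 79 genes, 30 moved by over 1.5 times when 1 line or another was left out. Those that moved without COLO741 were the 16 genes ABCA3, ETS2, FAS, BAK1, DDB2, FAP, FOSB, CHORDC1, HK2, HMGCS1, IL1B, FTL, RPS25, RPS7, CYC1 and TGFA, and without SW620 the 10 genes SLC12A2, CCND1, PLK2, DPP4, MLANA, LAPTM5, CHAC1, DDIT4, VEGFA and OR1N1. Without HT29 they were LGR5, MCM6 and HSPA1L, and without HCT116 FAP and OR3A3.

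Within single lines, differences between the 2 arrays reached 3.28 log2 units, with no replicate and no test. Of the 24 genes named for single lines, 13 had at least 1 array of that line under the 95th percentile of the olfactory receptor probe sets, so that their order by size is uncertain. With both arrays under it, SPRR2D in HT29 and ZNF717 and ZNF737 in HCT116 were at background. The others were PM20D2 and PCDHB8 in COLO741, CCL2, CYBB and FCER1G in SW620, SLC14A1 and AGMO in HT29, and TRIM29, LOC399975 and SSTR1 in HCT116, whose differences are read as lower bounds. In COLO741, 275 genes differed by at least 1 log2 unit, 231 higher in the array labelled ABCB5-positive and 44 lower, and ABCB5 itself opposed the label there. With the strict filter on dim genes, which tests fewer genes, the single cell line differences COLO741 had numbered 179. The highest were PSAT1, an enzyme of serine synthesis, at 2.88, the GM-CSF receptor gene CSF2RA at 2.78 and PM20D2 at 2.77, and the lowest were PCDHB8, of a clustered family, at -1.96, IRF4, a transcription factor of lymphocytes and melanocytes, at -1.71 and the cadherin gene CDH3 at -1.51. HT29 had 50 such genes, 46 higher and 4 lower, led by CLEC3A at 2.84, SLC14A1, a urea transporter, at 1.91 and PADI2 at 1.91, with AGMO at -1.40, SPRR2D, of a clustered family, at -1.18 and HHLA2 at -1.09. HCT116 had 5, with TRIM29 at 1.37, ZNF717 at 1.27 and ZNF773 at 1.15 highest and ZNF737 at -1.02, LOC399975 at -0.98 and SSTR1 at -0.97 lowest, the ZNF genes being of clustered families.

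SW620 had 104 genes at that size, 88 higher and 16 lower, and with the strict filter on dim genes the single cell line differences SW620 had numbered 58. The highest were CCL2, a chemokine that attracts monocytes, at 3.28, CYBB, the oxidase subunit of phagocytes, at 3.22 and FCER1G, an Fc receptor chain, at 2.45, and the lowest ALDH1A2, which makes retinoic acid, at -2.14, FN1, fibronectin, at -1.79 and F13A1 at -1.61. The leukocyte list had a median of 0.36 in SW620, above all of the 10000 random lists (percentile 100), with LYZ at 1.67 and CD14 at 1.37 (named after their values were seen). In COLO741, HT29 and HCT116 its medians were -0.08, -0.01 and 0.08. Epithelial genes had a median of 0.22 in SW620 (percentile 100) but -0.12 in COLO741 (percentile 3.95), -0.07 in HT29 (percentile 2.62) and -0.02 in HCT116 (percentile 42.9). Such percentiles take the genes of a list as independent within 1 pair of arrays and measure no spread between replicates. The olfactory receptor genes, by which dimness was judged, reached percentile 100 in HCT116 and 0.475 in HT29.

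**Figure D3:**
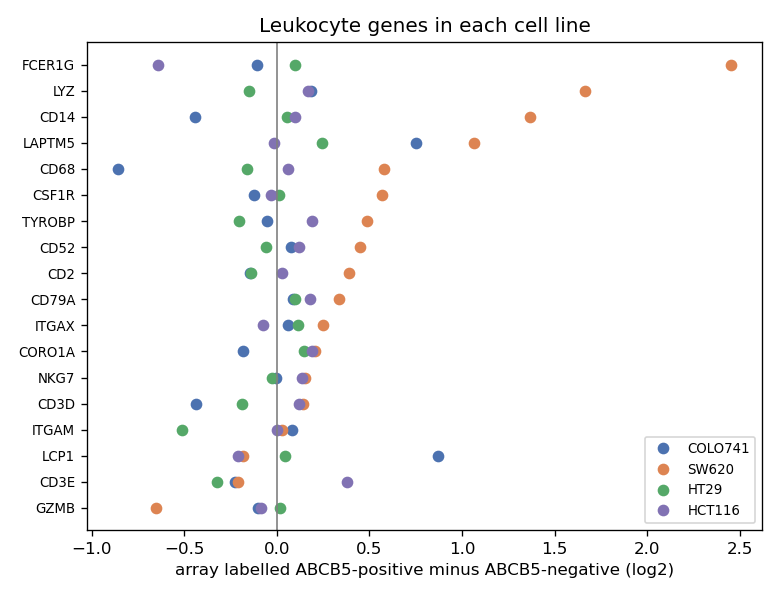
Difference of each leukocyte gene (log2, array labelled ABCB5-positive minus array labelled ABCB5-negative, horizontal axis), 1 point per cell line and no error bar because each line has 1 pair of arrays. In SW620 FCER1G stands at 2.45, LYZ at 1.67 and CD14 at 1.37.

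The agreement between lines was measured by correlating these differences across genes. Over the 6 pairs of lines, Pearson's r averaged 0.0229 ± 0.0591 (SD over pairs) and ran from -0.0730 for SW620 and HCT116 to 0.0967 for COLO741 and HT29, and Spearman's rho averaged 0.0231. As labelled, COLO741 had r of -0.0140 with SW620, 0.0967 with HT29 and 0.0361 with HCT116. An exchange of its 2 arrays would turn these signs, so the mean and the highest value rest on its labels. The agreement between cell lines by mean r was -0.0170 without HT29 and 0.0560 without SW620. These are correlations across genes, which are not independent replicates, and no line shares an array with another. Of the genes tested, 2260 had 1 sign in all 4 lines, 13.4% against 12.5% by chance. Over the 8 ways to swap the labels within lines this count ran from 1647 to 2767, the highest with SW620 swapped. With COLO741 exchanged it was 1848, so the small excess over 12.5% does not set the labels as given apart. A difference of at least 1 log2 unit occurred in 1 line for 416 genes, in 2 lines for 9 genes and in 3 or more for 0.

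Differences between the cell lines were far larger than those between the populations, and COLO741 stood apart by pigment cell genes. No line had a replicate culture, so the tests set differences between lines against the spread between the 2 sorted populations of a line. TYRP1, an enzyme of melanin synthesis, measured 8.26 ± 0.16 higher (log2, SE) in COLO741 (2 arrays) than in the other lines (6 arrays), and PMEL, which forms the fibrils of melanosomes, MLANA, a melanosome protein, and SLC24A5, an ion exchanger of pigment cells, were higher by 7.02, 7.18 and 7.39. GPNMB, GNG11, the protease gene MMP8 and the small nucleolar RNA SNORD116-14 were higher by 7.81, 7.70, 7.41 and 7.38. EPCAM, an adhesion molecule of epithelia, differed by -7.62 ± 0.22, DSG2, of desmosomes, by -6.77 and KRT8, a keratin of simple epithelia, by -6.15. ANXA3, ME1, SAMHD1, CENPV and HOOK1 differed by -7.09, -6.86, -6.54, -5.99 and -5.71. The lower level of 15 of these 16 genes, such as 5.74 for TYRP1 in the other lines and 5.90 for EPCAM in COLO741, lay under the 95th percentile of the olfactory receptor probe sets, so that their differences are read as lower bounds and not ranked. The highest limma adjusted p among these 16 genes was 4.80e-05, that of SNORD116-14.

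Of 17 melanocyte genes 16 passed as higher in COLO741, with a median of 4.98, and of 21 epithelial genes 20 passed as lower, with a median of -3.05. The melanocyte list rose with an adjusted p of 5.70e-12 and the epithelial list fell with an adjusted p of 1.67e-11 at the preset correlation, and both were at an adjusted p = 0.239 with an estimated correlation. In all, 8408 genes differed between COLO741 and the other lines, 4006 higher and 4402 lower, of which 116 were at least 4 log2 units higher and 60 at least 4 lower. Between any of the lines 11370 genes differed, 67.2% of those tested, again against the spread between the sorted populations and not between cultures. The lines accounted for 96.4% of the variance of the log2 values and the sorted populations for 0.964%, with 2.63% left on 3 residual degrees of freedom. The share of the populations was thus close to what was left per degree of freedom.

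**Figure D4:**
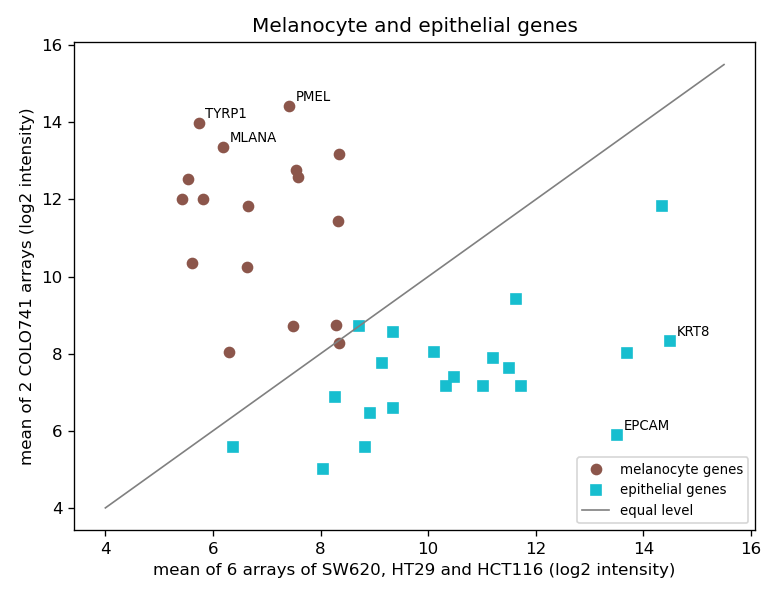
Mean log2 level in the 2 COLO741 arrays (vertical axis) against the mean of the 6 arrays of SW620, HT29 and HCT116 (horizontal axis), 1 point per gene, brown circles for melanocyte genes and blue squares for epithelial genes, with the line of equal level. TYRP1, MLANA and PMEL lie far above the line and EPCAM and KRT8 far below it.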

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

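The tests of RNA from the other lines, of exchanged labels and of the neighbours of the largest differences were chosen only after the result was seen. Of 111 sets of 4 values, 1 per cell line, 8 held a line far from the other 3, where chance gives about 1 in 20. ABCB5 stood apart in COLO741, at 9.418 among the ABCB5-negative arrays and 8.141 among the ABCB5-positive arrays. Among the differences between populations, COLO741 stood apart for BAK1 at -0.4278, for FTL at -0.7009 and for the median of the DNA replication and S phase genes at 0.1414. SW620 stood apart for PLK2 at 0.5549, for PRTG at -0.2713, nearer to 0 than in the other lines, and for the median of the respiratory chain genes at 0.0901. The olfactory receptor genes moved in opposite directions in HT29, with a median of -0.05734, and in HCT116, with 0.09016, and the difference between these lines was not tested.

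In COLO741 the array labelled ABCB5-positive had 231 genes at least 1 log2 unit higher and 44 lower, while the ABCB5 transcript was lower. RNA of the other 3 lines is argued against as the source, since the 3 genes dim in the COLO741 negative array and at 12 or more in those lines differed by a median of 0.307 (PM20D2 2.77, ANXA3 0.31, EPCAM -1.06) and the 13 genes at 11 or more by 0.05, with EHF at 1.29 and ULBP3 at 1.21 as the others over 0.5 and, of further epithelial genes, KRT8 at 0.46 and KRT19 at -0.12, against 2.39 for the 28 genes that differed by over 2. An exchange of the 2 COLO741 labels cannot be told apart from the labels as given, because the mean correlation with the other lines, 0.03961, lies within their own range of -0.0730 to 0.0563, and 5 lists kept 1 sign in all lines as labelled against 3 with COLO741 turned, where 1 list passed (adjusted p 0.0288) and 0 of the 5 called as labelled. Neighbouring genes had a rank correlation of 0.1942 in COLO741, against 0.0534 in SW620, 0.0375 in HT29 and 0.0437 in HCT116, also above their own shuffles, and at most 0.0224 in 1000 shuffles of COLO741. Between genes 10 apart it was 0.115 in COLO741 against 0.006, 0.018 and 0.009 in SW620, HT29 and HCT116. Of 304 blocks of 40 genes in chromosome order, 59 had a median beyond 0.15 in COLO741, against 2, 1 and 0. Such small shared shifts could reflect a difference in gene copy number between subpopulations of COLO741, a hypothesis from RNA alone. The same explanation is argued against for the 215 placed genes at least 1 log2 unit higher, whose nearest 5 genes on either side had a median of 0.03629 ± 0.0179 (bootstrap SE) and reached 0.5 for 1 gene, and an effect of ABCB5 itself stays open as untested with 1 pair of arrays.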

How the results depend on the processing

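The setting without COLO741 and SW620 together, and its values, were chosen only after the data had been seen. The count of genes past an adjusted p of 0.05 was 0 under every alternative, and 5 genes passed the looser threshold of an unadjusted p under 0.01 with at least a 1.5-fold difference. The genes with unadjusted p under 0.05 numbered 27 with no replicate block, 1431 over every probe set, where more features are tested, and 526 to 818 under the other alternatives except the one added, with 835. Genes with unadjusted p under 0.01 and at least 1.5-fold numbered 0 with no block, 1 with the line as a random block, 3 under the strict filter, 1 without moderation, 31 over every probe set, 8 without SW620, 23 without HCT116 and 13 without COLO741 and SW620. Without the block the adjusted p of mesenchymal and invasion genes was 0.2386, and it was 0.06299 with the line as a random block and 0.05642 without COLO741 and SW620, so that this list lost its call in all 3 settings. The block changed no other call.

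The number of lists called was 8 over every probe set, which added ABC transporters, leukocyte genes and receptor tyrosine kinases, and 0 with an estimated correlation or by fry. With an estimated correlation the adjusted p was 0.5802 for the G2/M genes and 0.5478 for the other 4 lists, and by fry 0.4008 for all 5. Under the other alternatives 4 to 7 lists were called. Leukocyte genes were also called with no filter, under the strict filter, without COLO741 and without HT29, cholesterol synthesis genes without SW620 and without COLO741 and SW620, and receptor tyrosine kinases and olfactory receptor genes without HCT116. The ABCB5 transcript level, as its mean difference, ran from -0.4339 without HCT116 to 0.08776 without COLO741, where it turned sign on values at background, and was 0.08364 without COLO741 and SW620. ABCB5 was too dim for the strict filter, which gave it no value. Without COLO741 and SW620 the difference of SLC12A2 turned to 0.00745, the difference of FAP to -0.02002 and the difference of VEGFA to -0.015. With ABCB5 left aside, 1523 of 1526 values of named results over all settings kept their sign. Under the strict filter, which tests fewer genes, the single cell line differences COLO741 showed numbered 179 and the single cell line differences SW620 showed 58. The causes of the other changes were not tested. The counts between cell lines and the mean correlation between lines stayed within 1.5 times or 1 SD of the reported values. Quantile normalization and median centring moved the median of all genes by at most 0.03 and 0.05. Dim genes such as ABCB5 outside COLO741 limit what the signal over background can show.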

Other observations

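The tests of an NF-kB or interferon response and of cycling cells were chosen only after the result was seen. Named after their values were seen, 9 genes reached 1 log2 unit in 2 lines. Of these, AXL, TGM2, MCUB and MYEF2 did so in COLO741 and HT29, with MCUB at 1.81 and 1.28 and MYEF2 at 1.04 and 1.42. GLIPR1 measured 1.45 in COLO741 and 1.70 in SW620, and GPX8, an endoplasmic reticulum peroxidase, 1.11 in SW620 and 1.32 in HT29. The other 3 genes had opposite signs, ANTXR2 with 1.14 in COLO741 and -1.32 in SW620, SYTL5 with 2.48 and -1.49 in the same lines, and SLC14A1 with -1.59 in SW620 and 1.91 in HT29. None of these values has a test.

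Of the mesenchymal list, AXL was high in both COLO741, at 1.12, and HT29, at 1.01, and the 3 members with the highest values in each are named here after their values were seen and without a test. In COLO741 they were ZEB1, a repressor of E-cadherin, at 2.39, the matrix gene TNC at 1.80 and the collagenase gene MMP1 at 1.46, and in HT29 S100A4 at 1.20, TGFB1 at 1.19 and TGFBI at 1.13. In SW620 the epithelial genes CDH1, which encodes E-cadherin, TSPAN8 and GRHL2 measured 1.48, 1.43 and 0.97, and the mesenchymal list had a median of 0.07 (percentile 90.2), with FN1 at -1.79 and ZEB1 at -0.58 but PLAU at 0.52 and AXL at 0.11. In COLO741 the melanocyte median was -0.17, with TRPM1 at -1.02, GPR143 at -0.96 and OCA2 at -0.95. As background, cell line catalogues list COLO741 as a melanoma line, whereas the labels give colon carcinoma. In these data 16 of 17 melanocyte genes were higher and 20 of 21 epithelial genes lower in COLO741 than in the other lines. This profile goes with the catalogues, though the origin of the line was not tested. Means over the 4 lines pool COLO741 with 3 lines that do not share it.

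In the SW620 array labelled ABCB5-positive, transcripts of phagocytes such as CYBB, FCER1G and LYZ were higher. RNA of macrophages or monocytes is a candidate source that cannot be told apart from expression by the SW620 cells, since 41.67% of its dim listed genes (5 of 12) were brighter by over 0.5, above the 16.7% that bounded random lists but not most of them, and 0 of 4 dim genes of T, B and NK cells were. The 5 were CTSS (6.10 to 6.83), FCGR2A (5.77 to 6.93), AIF1, CD163 and CD86, all still under the 95th percentile of the olfactory receptor probe sets. Among the other dim genes, S100A9 went from 7.25 to 7.37 and C1QA from 6.69 to 6.34. Both lay under that percentile on all 8 arrays, so they may be at background throughout. Genes outside the added lists, named after their values were seen, did rise above it in SW620. MPEG1 went from 6.77 to 8.38, CD53 from 6.99 to 8.26 and SRGN from 7.01 to 8.91. Of the listed macrophage genes above it in the negative array, ALOX5AP went from 7.59 to 8.33 but C1QC from 7.64 to 7.32. In the SW620 negative array 6 of the 18 macrophage genes and 6 of the 10 T, B and NK genes tested were bright. An induced NF-kB or interferon response cannot be told apart either, with a median of 0.1718 ± 0.0844 (bootstrap SE) for the interferon-stimulated genes and 0.08 ± 0.07 for NF-kB targets beside 0.33 ± 0.24 for the dim leukocyte genes and 0.18 ± 0.25 for the dim macrophage genes, medians within overlapping errors. The sort was on ABCB5, not on a leukocyte marker, 0 of the macrophage genes are in the leukocyte list, and over all lines the added lists of macrophage and of T, B and NK transcripts had unadjusted camera p-values of 0.355 and 0.897 with limma.

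At the preset correlation small nucleolar RNAs were dimmer and mitosis genes brighter in the arrays labelled ABCB5-positive, calls lost with an estimated correlation (adjusted p 0.548 and 0.580) and by fry (0.401 for both), with 0 members of either list past over all genes by limma and 38 and 11 at an unadjusted p under 0.05. For the small nucleolar RNAs a loss of short RNA during preparation may contribute, since 128 other short RNA genes had a median of -0.04231, below nearly all random lists (percentile 0.03). Their unadjusted limma camera p was 2.12e-04 at the preset correlation, and no estimated correlation was run for this list. By line their medians were -0.02 in COLO741, -0.11 in SW620, -0.07 in HT29 and 0.02 in HCT116. The small nucleolar RNA medians ran in another order, at -0.28, -0.06, -0.08 and -0.17 in the same lines. COLO741 and HCT116, lowest for the small nucleolar RNAs, thus had the other short RNAs nearest 0, which a shared loss does not account for. The pooled median of the other short RNAs is nearer to 0 than the -0.14 of the small nucleolar RNAs, and the test does not bear on the mitosis genes. More cycling cells cannot be told apart from other sources for the mitosis and histone genes, since the S phase median of 0.01431 lay at percentile 94.9 of random lists, with 0.14 in COLO741 and -0.01, -0.03 and -0.02 in SW620, HT29 and HCT116. A biological difference between the populations stays open.

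Other arrangements of the labels bear on the number of lists. Of the 8 ways to swap the labels within lines, the labels as given among them, 5 gave at least the real 5 lists. The highest of the others gave 8, and 8 ways are too few for a share under 0.05. Every way called at least 1 list at the preset correlation. The G2/M, histone and small nucleolar RNA lists were also called with SW620, HT29 or HCT116 swapped alone. For the count of genes the comparison carries no information, since the real count was 0 by limma, with 744 at an unadjusted p under 0.05, and no arrangement can give fewer. All 8 swaps within lines and all 35 splits of the 8 arrays made without regard to line therefore reached it, with 0 and 888 genes as the highest of the others. The split with 888 genes set both COLO741 arrays and both HT29 arrays against the rest, and the splits that paired COLO741 with HCT116 and with SW620 gave 807 and 746, which points to the structure of the cell lines.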
